A study of Mus musculus with 4 samples.

How the data were processed

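CTCF, a zinc-finger protein that binds DNA at chromatin domain borders and loop anchors, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 4 tissues of wild-type mouse embryos of a B6CBAF1 background, with 1 library per tissue. Per the labels, posterior trunk was taken at embryonic day (E) 10, from about 30 embryos staged E9.75 to E10 in the protocol. The dissected piece held the tailbud, the presomitic mesoderm and a few somite pairs, with the hindlimb buds left out as far as possible. Brain was a pool of telencephalon from 6 embryos at E12.5. Distal and proximal forelimb were both from E12.5, and their titles mark them as data of an earlier study that were analysed again. Grouping followed the tissue given in the labels. With 1 library per tissue no difference between tissues has a replicate check, so no p-value across libraries is given.

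Per the submitters' processing notes, the tools were cutadapt 1.16, Bowtie2 2.3.5, SAMtools 1.9 and MACS2 2.1.1.20160309, and the genome build was mm10. Their options, and whether an input library served as control, are not given in the sources used here. The authors deposited 1 peak list per library, in the narrowPeak layout. Each row of the deposited lists holds a fold, which is the ratio of the summit pileup to the local background with a pseudocount of 1 on both. It also holds a −log10 p-value and a −log10 q-value at the summit, as the authors' caller wrote them. The deposited score equals 10 times the −log10 q cut to a whole number in at least 99.98% of rows of each list, and the summit is given as an offset in bases. The lowest −log10 q was near 1.30 in each list, which is a q of 0.05. Folds are the authors' values. They and the ranks computed from the authors' p describe peaks within their own list only.

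Rows with the same interval and several summits were merged to 1 peak with the strongest summit. Chromosomes 1 to 19, X and Y were used, and coordinates are 1-based on mm10. Peaks of the 4 lists were joined into union regions when they shared at least 1 base. A region was counted for a tissue when a peak of that tissue lay in it. Overlap between lists was computed with bedtools 2.31.1 and set beside the mean of 20 random shifts of 1 list within chromosomes. The rank percentile of a peak is its place by p within its own list, with the strongest peak at 100. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

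The lists give no read totals, so the absolute depth is unknown. Fold and p together gave back a whole pileup and a local background for each row, with an error in −log10 p of at most 0.00034. The lowest background of a list scales with its depth, and it was 9.34 in posterior trunk, 8.53 in brain, 4.23 in distal forelimb and 4.58 in proximal forelimb. Relative to distal forelimb the depths were 2.21, 2.02, 1 and 1.08. For each region absent from a list, the chance of its being called there at the same occupancy was computed by scaling pileup and background by relative depth. The pileup was the one seen where the region was called, so such chances lean high for regions near the threshold. The highest pileups were 399, 393, 368 and 365, all under 400, the most that 1 read start per base and strand would give with the 200-base extension read from the background steps. Whether repeated reads were removed is not given in the sources used here. If they were, high folds in the deeper libraries are compressed. In tests on simulated data, 100% of 20000 pileups and 100% of 5000 tissue patterns were recovered. The simulated regions had equal widths and lay far apart, so the joining of close neighbours was not tested.

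Gene positions came from the RefSeq genes of GRCm38.p6, the same assembly as mm10, and all 180 listed gene symbols were matched. This table gives gene spans without strand or exons, so distances are to the gene span and not to a gene start. A list gene's window was its span with 50 kb on both sides, and closeness to a gene means within 1 kb of either end of the span. The planned motif searches, site orientation and exon or intron location need a genome sequence or transcript models and were not run. For each of 8 gene lists, the share of one-tissue regions in the windows was set against 10000 random lists of the same size matched on the number of union regions per window. Trunk-only counts over the Hox clusters were set against 10000 sets of random windows of the same lengths, matched on regions called in all 4 tissues or on gene ends. Such percentiles describe these libraries and are not p-values.

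The genes and regions named follow a rule fixed before the data were examined, as were the gene lists. The rule takes every region from Evx2 to Mtx2, and per tissue the 10 regions called there only with the highest fold. It also takes, per tissue, the 5 regions missing there only with the highest lowest rank percentile elsewhere. Up to 4 members per list with a one-tissue region nearby were named by fold, together with the imprinted and protocadherin loci. A few items that the rule takes are not reported here. Regions of HoxA, HoxB and HoxC named singly and the densest 200 kb bins were chosen after their values were seen. The alternatives were a −log10 q of at least 5, lists of equal length, pileups thinned at random with a common −log10 p of at least 5, summits within 100 bases, a reciprocal overlap of 0.5, autosomes only and a gene window of 100 kb. For the thinning, the recovered summit pileups of called peaks, not reads, were thinned so that the lowest backgrounds of the lists matched. Depth is thus matched by that value only, and peaks outside the lists cannot enter. Counts with the common p threshold but no thinning, counts without the posterior trunk library, and Hox counts with each cluster left out, were added after seeing the data.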

Results

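CTCF peak lists were compared between 4 embryonic mouse tissues, posterior trunk at E10 and brain, distal forelimb and proximal forelimb at E12.5. The study's title concerns CTCF sites of the Hoxd cluster, a row of homeobox genes that pattern the trunk and the limbs. The comparisons address which sites were shared by these tissues, there and across the genome. Posterior trunk had 106662 peaks, brain 74127, distal forelimb 64793 and proximal forelimb 63873. Median peak widths were 379, 361, 363 and 363 bases. Posterior trunk and brain were the deeper libraries, at 2.21 and 2.02 times the relative depth of distal forelimb. Each tissue had 1 library, so no difference below has a replicate check, and a region counted for 1 tissue only means one called in that library and in none of the others.

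The 10 CTCF regions called in every tissue across Hoxd all lay in the part of the cluster from Evx2 to Hoxd3, on chromosome 2 of mm10. Evx2, a homeobox gene at the end of the cluster next to Hoxd13, held the regions 74655193–74655751 and 74655811–74656111. Between Evx2 and Hoxd13 were 74661460–74662198, which began just inside the span of Evx2, and 74663488–74664014. Between Hoxd13 and Hoxd12 was 74672939–74673350. The span of Hoxd10 held 74686188–74686851, which also lay in the span of Hoxd11, together with 74691597–74691978 and 74693958–74694494. The row ended with 74702115–74702679 between Hoxd9 and Hoxd8 and 74715642–74716410 in the span of Hoxd3. The last of these ranked at percentile 91.7 of the trunk list, 87.9 of brain, 88.1 of distal forelimb and 86.4 of proximal forelimb. The weakest was 74655811–74656111 in Evx2, at percentiles 21.5, 20.3, 24.6 and 28.0.

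Posterior trunk had 13 further regions between Evx2 and Mtx2, a gene beside Hoxd1 that is not a homeobox gene. The region 74697618–74697921, which began between Hoxd10 and Hoxd9 and reached into the span of Hoxd9, was also called in brain. The other 12 were called in trunk only. The highest authors' folds among these 12 were 4.84 at 74751135–74751515, in the span of the non-coding gene Haglr between Hoxd3 and Hoxd1, and 4.69 at 74670679–74671054 in Hoxd13. The remaining 10 were at percentiles under 30 of the trunk list, with the lowest fold of 2.07 at 74730199–74730418 in Hoxd3. They were 74678993–74679412 between Hoxd12 and Hoxd11, 74710368–74710567 between Hoxd8 and Hoxd3, 74723082–74723496 in the spans of Hoxd3 and Hoxd4, and 74730199–74730418. Haglr held 74749903–74750117, 74752987–74753192 and 74760097–74760380, and beyond Hoxd1 were 74787728–74787989, 74790097–74790345 and, in Mtx2, 74858083–74858323. At the same occupancy, 11 of the 12 would have been called in brain with a chance of at least 0.95. In distal forelimb this held for only 2, and in proximal forelimb for 3. The value for brain was largely fixed in advance. These regions were picked for passing in trunk, and brain was nearly as deep, at 2.02 against 2.21. It therefore does not show that brain lacks them. After pileups were thinned to the same lowest background, with a common −log10 p of at least 5, the trunk total went from 23 to 14. Of these, 9 were called in all 4 tissues and 5 in trunk only, while brain and both forelimb parts had 10 regions each. The 5 were 4 of the 12 and the region 74697618–74697921 at the end of Hoxd9, which was no longer called in brain.

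**Figure D1:**
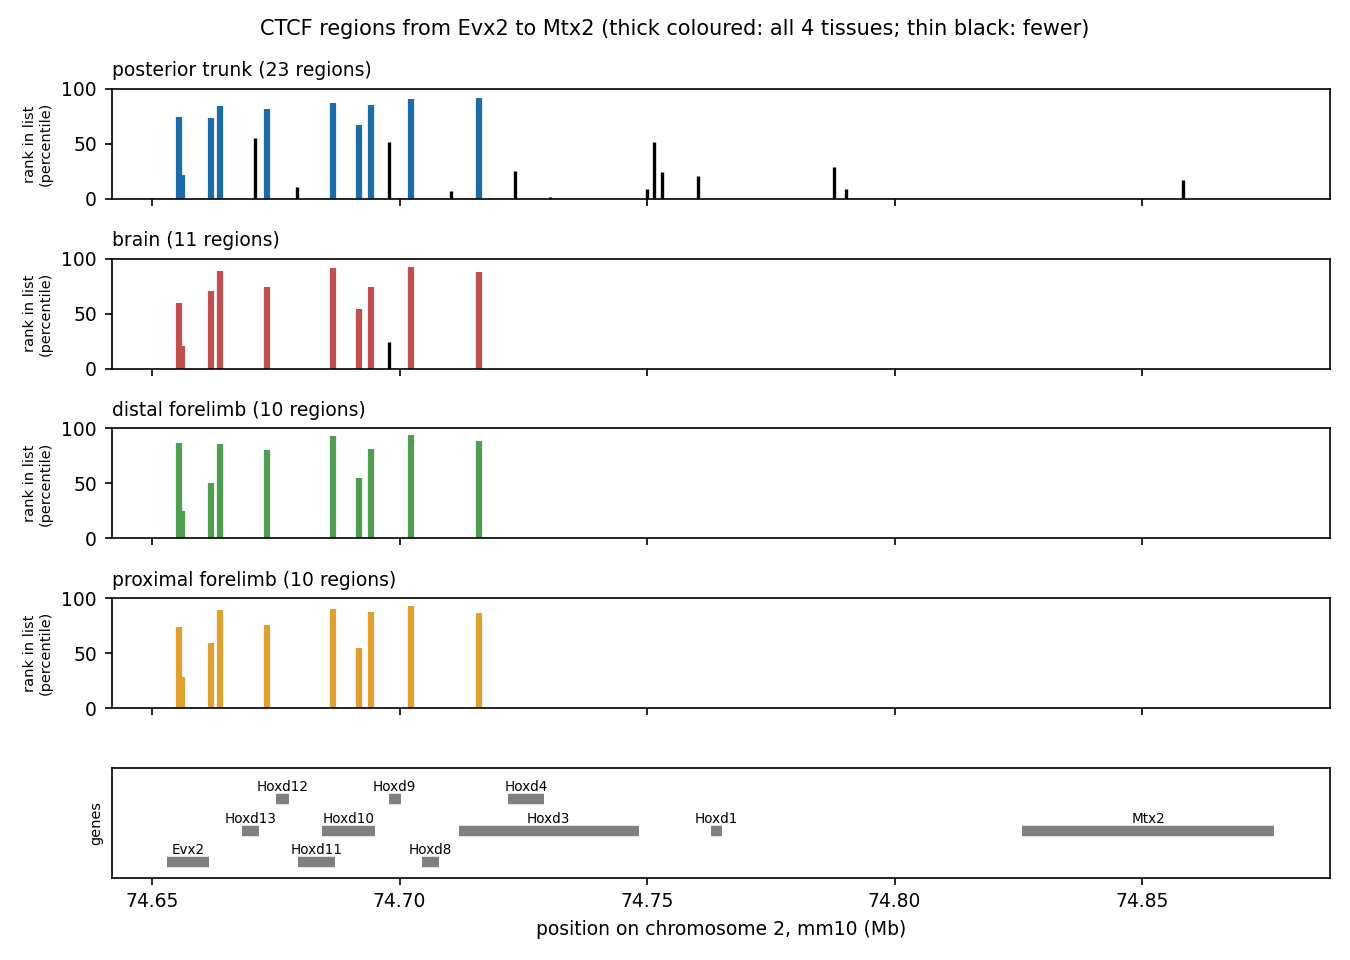
CTCF regions from Evx2 to Mtx2 by position on chromosome 2 (Mb, mm10) in the 4 tissues, with bar height giving the rank percentile within each tissue's own list and gene spans at the bottom. Thick coloured bars are the 10 regions called in all 4 tissues, which end in Hoxd3, and thin black bars are called in fewer tissues, 12 of them in posterior trunk only.

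The megabase on each side of Hoxd also held shared regions. On the Evx2 side, 21 of 63 regions were called in all 4 tissues and 25 in posterior trunk only. On the Mtx2 side these were 30 and 22 of 67.

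The other Hox clusters differed in how much of their CTCF occupancy was shared. HoxB had 12 of 23 regions called in all 4 tissues and HoxA 11 of 28, while HoxC had 4 of 22. Regions called in posterior trunk only numbered 15 in HoxC, 9 in HoxB, 8 in HoxA and 9 in HoxD from Evx2 to Hoxd1. In the same order these trunk-only counts were 9, 4, 4 and 3 after thinning, and 3, 3, 2 and 2 in lists of equal length. HoxC regions of this kind with the highest folds were 103002124–103002548 in Hoxc6, at 6.13, and 103030925–103031288 in Hoxc4, at 5.93, both on chromosome 15. A region between Hoxc12 and Hoxc11, 102943256–102943785, was called in trunk at a fold of 8.41 within its list and in brain, and in neither forelimb part. The 41 trunk-only regions of the 4 clusters exceeded each of 10000 sets of random windows matched on shared regions, whose median was 12 and highest value 31. After thinning the 4 clusters had 20, against 13 at the upper end of the central 95% of random sets. Leaving out HoxC gave 11, at percentile 97.1. In lists of equal length and with a −log10 q of at least 5, the clusters without HoxC stood at 99.86 and 99.94. These last settings do not match depth. Singly, after thinning, HoxA, HoxB and HoxD stood at percentiles 89.0, 84.4 and 88.1, and HoxC at 99.98.

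**Figure D2:**
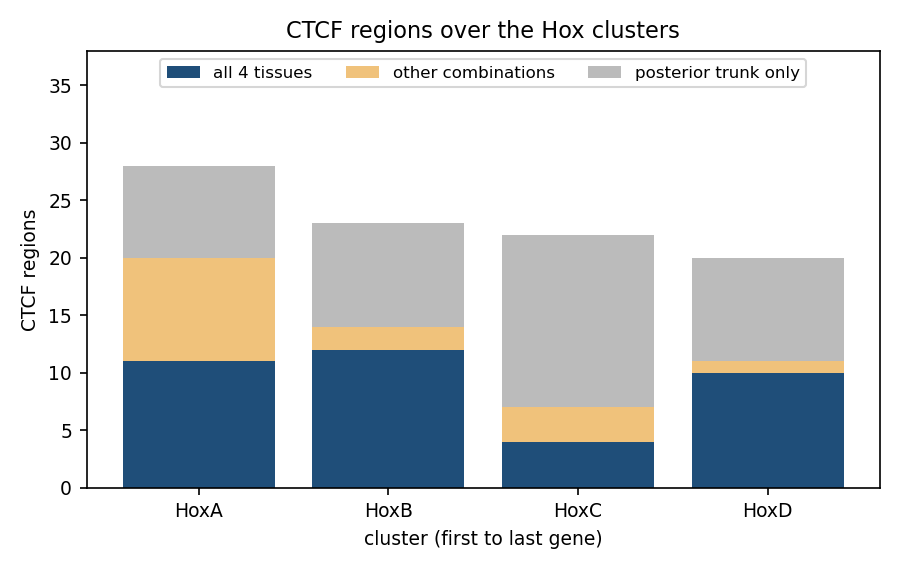
Number of CTCF regions over each Hox cluster, stacked by the tissues in which they were called. In the lists as deposited, HoxC has 15 trunk-only regions of 22, and HoxB has 12 of 23 called in all 4 tissues.

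HoxA was the cluster in which both forelimb parts had regions absent from brain. Around Hoxa13, a gene of the distal limb, 3 regions were called in both forelimb parts and trunk but not in brain, namely 52248625–52248916 between Hoxa11 and Hoxa13, and 52280688–52281276 and 52291704–52292043 between Hoxa13 and Evx1, on chromosome 6. The region 52264852–52265129, 4.10 kb from Hoxa13, was called in distal forelimb only, with a fold of 6.29. Proximal forelimb alone had a region in Hoxa10, 52235015–52235219, with a fold of 3.98. Another distal-only region, 52317007–52317230 in Evx1, had a fold of 3.79. Brain alone had 52229078–52229278 between Hoxa9 and Hoxa10, at 3.01, and brain and distal forelimb shared 52289164–52289377 between Hoxa13 and Evx1. HoxB, HoxC and HoxD had 0 regions of the first kind.

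Across the genome, the strongest CTCF regions of each list were nearly all called in all 4 tissues, and regions called in 1 tissue were mostly weak. The 121759 union regions included 51657 called in all 4 tissues, or 42.4%, and 48233 called in 1 only, or 39.6%. Posterior trunk accounted for 34525 of the latter, brain for 7213, distal forelimb for 3784 and proximal forelimb for 2711. The shared regions were 48.5% of trunk regions, 70.2% of brain, 80.4% of distal forelimb and 81.6% of proximal forelimb regions. Median rank percentiles of the one-tissue regions were 19.9 in trunk, 7.19 in brain, 5.40 in distal forelimb and 5.26 in proximal forelimb. In the eighth decile by rank, 98.8% of trunk peaks and 99.9% of brain peaks lay in regions called everywhere, against 1.57% and 6.31% in the weakest decile. This trend is largely built in, since a weak region is more easily missed in another list even at equal occupancy. It does not show that strong and weak sites differ in how far tissues share them. These one-tissue counts changed with the setting. Trunk-only regions were 31249 with a common −log10 p of at least 5, 19341 when pileups were also thinned and 5455 in lists of equal length, and brain-only regions were 4264, 2406 and 4016. With a −log10 q of at least 5, brain-only regions were 2338, distal-forelimb-only 820 and proximal-forelimb-only 788.

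**Figure D3:**
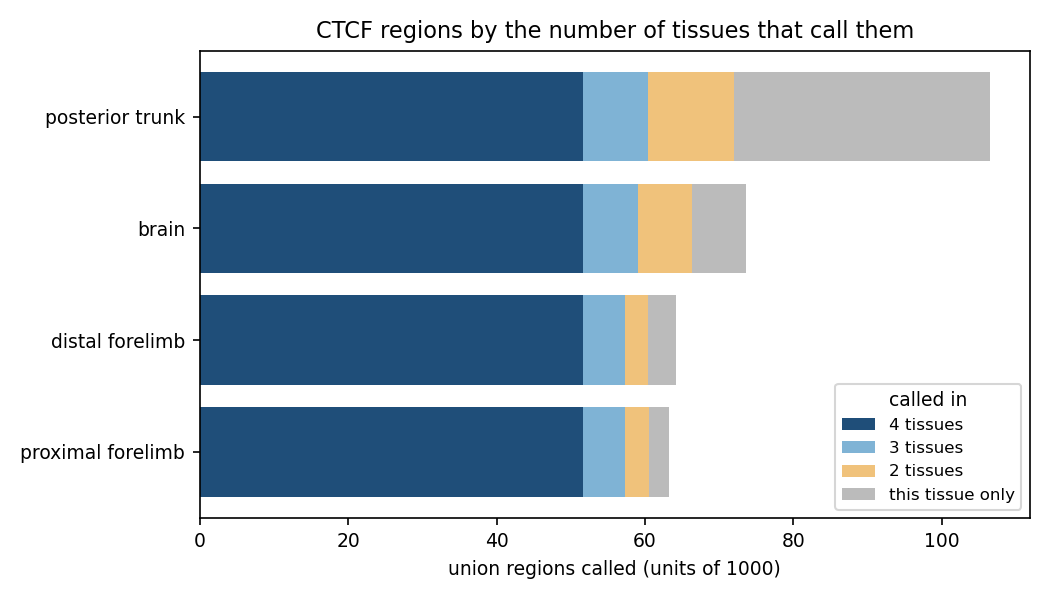
Union regions called in each tissue, on an axis in units of 1000 regions, stacked by how many tissues called them. The 51657 regions common to all tissues form the left part of each bar, and posterior trunk has the longest part of its own, 34525 regions.

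**Figure D4:**
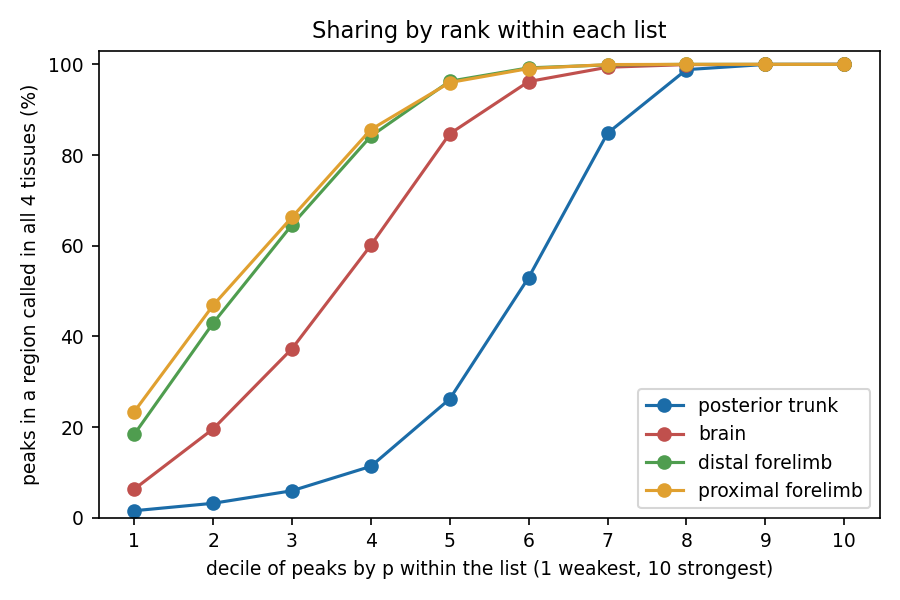
Share of peaks (%) in a region called in all 4 tissues, by decile of p within each list from weakest (1) to strongest (10). The share climbs from 1.57% to 100% in posterior trunk and from 23.4% to 100% in proximal forelimb.

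Between pairs of tissues, both forelimb parts overlapped each other in similar shares, with 84.3% of distal peaks found in proximal forelimb and 85.5% in the other direction. Posterior trunk held 88.8% of brain peaks, 92.4% of distal and 93.9% of proximal forelimb peaks. Conversely, 61.3%, 55.7% and 55.8% of trunk peaks were found in these tissues. Brain peaks were found in 75.9% of cases in either forelimb part, and brain held 87.0% of distal and 88.2% of proximal peaks. Shifted lists overlapped by 1.91% to 3.37%. Over bases, the Jaccard index was 0.697 for the forelimb pair and 0.481 for trunk and distal forelimb in the lists as deposited, and 0.529 for trunk and brain. At equal length trunk and brain shared 54867 regions, more than the 54092 of the forelimb parts.

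The strongest regions of distal forelimb alone included sites at developmental regulators. Cdx4, a caudal-type homeobox gene, held chromosome X 103321497–103322058, with a fold of 7.43, and Meis1, a homeobox gene of the proximal limb, held chromosome 11 19018274–19018972, at 6.03. The region near Hoxa13 lay between them by fold. Ahead of these were regions 14.1 kb from Ttc28, at 8.54, and in Smyd3, at 7.77, and the others of the leading 10 were nearest Nectin3, Olfr875, Emb, Fyn and Usp29. Each of these 10 would have been called in each other library at the same occupancy with a chance of at least 0.95. For strong regions of the shallowest library this was largely fixed in advance.

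Among brain-only regions, the highest fold, 9.16, was 101 kb from Cpsf6. Another was 141 kb from Sox2, a transcription factor of neural progenitors, at chromosome 3 34509145–34509527, with a fold of 7.36. Gpm6a, a neuronal membrane glycoprotein gene, held chromosome 8 54955912–54956265, at 8.18, and a region 5.89 kb from Cbln2, which encodes a synaptic organizer, had 7.22. The remaining regions of the leading 10 were nearest Pmfbp1, Dnajc19, Chodl, Pdzrn3, Tmem182 and Ptprn2. In posterior trunk alone the highest folds were 11.2 in Serpina1f, 10.7 at 27.1 kb from Nrsn1 and 10.5 at 246 kb from Irx1, a homeobox gene. Rbms3, Agbl1, Cpa6, Mon1b, Robo1, Cylc2 and Tle4 were nearest the others. Proximal forelimb began with a region 69.7 kb from Adgrg6, at 5.89, and others of its leading regions were nearest Gm21293, Gria2, Macroh2a1, Srfbp1, Matn2, Sertad2, Slamf7 and Atp8a2.

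Regions missing only from trunk were fewer than those called only there in each setting run. For the other tissues the order turned with the setting, as for brain, with 1791 missing against 7213 of its own as deposited and 2956 against 2406 after thinning. Brain lacked 1791 regions called in the other tissues, led by those in Arhgef3, 17.9 kb from Plxna4 and 18.8 kb from Itpr1, and then Btbd9 and Col27a1. Posterior trunk lacked 352, led by chromosome 14 109660335–109660743, whose nearest gene Slitrk1 lay 746 kb away. It was followed by regions in Tbc1d22a, 55.45 kb from Ubxn2b, 84.0 kb from Gm52481 and 35.0 kb from Lrrc4c. Distal forelimb lacked 3469, led by regions 155 kb from Ntrk2 and in Dpysl3. Next were those 29.3 kb from Zfat, 186 kb from Pcdh17 and 5.02 kb from Zfp949. Proximal forelimb lacked 3539, with Srrm4, Dlg2, Gm973 and Car7 among the nearest genes of the leading regions. Thinning gave 682 for trunk, 2956 for brain and 1982 for distal forelimb.

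Hox genes were the list with the largest trunk-only share. Of the regions around the 41 Hox and Evx genes, 45.5% were trunk-only, above the random lists in all settings run, whose median was 26.3% in the lists as deposited. Their windows overlap, so regions count for several genes. The random lists drew their genes singly across the genome and were not matched on such overlap. The comparison can therefore overstate how far the Hox list stands out. Known CTCF loci went the other way, with 13.2% trunk-only against 25.9% and percentile 0, and with 8.02% brain-only, at percentile 97.9. Of these loci 12 had a brain-only region as deposited, 4 with a −log10 q of at least 5, 5 at equal length and 2 after thinning. Some of these windows overlap too, as at Xist and Tsix and in the protocadherin clusters, so the same limit applies to their percentiles. Housekeeping genes were at percentile 39.5 for trunk-only regions. Lists and tissues made 32 combinations in all.

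Forelimb bud genes had more distal-forelimb-only regions than most random lists. Of 30 genes, 11 had such a region nearby, led by Meis1 at a fold of 6.03, Msx1 at 4.08, Hand2 at 3.83 and Tbx15 at 3.76. The share was 4.27% against a random median of 2.02%, at percentile 99.4, and 90.9 after thinning. The same list was also high for trunk-only regions, at 30.5% against 25.9% and percentile 95.7, and 11 of its genes had a brain-only region, at percentile 67.7, which became 4 with a −log10 q of at least 5, 5 at equal length and 2 after thinning. Proximal-forelimb-only regions lay near 5 of the 30, among them Fgf10 at 3.94 and Tbx5 at 3.55, at percentile 36.9. Telencephalon genes had brain-only regions near 8 of 30, among them Lhx2 at 3.28, and stood at percentile 34.7. That value was 98.5 after thinning and 99.7 at equal length. All 30 tailbud and presomitic mesoderm genes had a trunk-only region nearby, with Cdx4 at 5.78, Msgn1 at 5.52 and Dll1 at 5.08, but their share of 25.1% was at percentile 43.3. The count was 11 at equal length and 20 after thinning, and the percentile went from 8.56 after thinning to 93.7 with a 100 kb window. Markers of tissues that the dissections could also hold gave percentile 94.6 for trunk-only and 92.2 for brain-only regions near the 10 blood and endothelial genes, led by Gata1 at 5.95. Those with a brain-only region went from 6 to 1 after thinning or with a −log10 q of at least 5, and to 2 at equal length. For the 3 hindlimb markers, Tbx4, Pitx1 and Isl1, trunk-only regions stood at percentile 88.6 and proximal-forelimb-only regions at 98.6, the latter near Tbx4 alone.

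Most CTCF regions of the protocadherin clusters, where CTCF takes part in promoter choice, were shared by all tissues. Over the Pcdhg cluster 21 of 24 regions were called in all 4 tissues, over Pcdha 17 of 24 and over Pcdhb 17 of 29. From H19 to Igf2, an imprinted pair with a CTCF-bound control region, 4 of 5 regions were common to all tissues and the other was trunk-only. Grb10 had 6 shared regions of 11 in its window, Rasgrf1 5 of 8, Peg3 5 of 8 and Meg3 7 of 18, while Plagl1 had 3 of 9, Mest 2 of 6, Snrpn 5 of 13 and Kcnq1ot1 0 of 2. On the X chromosome, Xist and Tsix, overlapping non-coding genes of X inactivation, had 6 of 9 and 7 of 11.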

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

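No test in this part was run beyond counting. Peaks outside chromosomes 1 to 19, X and Y were left out of all comparisons. The mitochondrial sequence held 22 peaks in posterior trunk, 22 in brain, 19 in distal forelimb and 18 in proximal forelimb. Unplaced and unlocalised sequences held 126, 142, 90 and 87 peaks in the same order. These drew attention as signal in data that no comparison used, with no control library here to set them against.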

How the results depend on the processing

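The common p threshold without thinning and the count without the posterior trunk library were chosen after seeing the data; the other settings were planned. Regions called in all 4 tissues stayed within 1.5 times 51657 in each setting run, and 52009 were called in the 3 other tissues when posterior trunk was left out. Motif searches under other windows and thresholds were not run, as no genome sequence was used here. No paired analysis was possible because each tissue had 1 library. Of the counts, those that moved by over 1.5 times were 19 of 67 with the stricter q, all down, 24 of 63 at equal length (16 down, 8 up), 16 of 67 after thinning (12 down, 4 up), 1 of 47 for close summits and 3 of 47 for reciprocal overlap, all up, 11 of 32 with the wider window, all up, and 0 of 47 on autosomes. The depth of single regions limits weak calls: of the 12 trunk-only regions over HoxD, 2 would have been called in distal forelimb with a chance of at least 0.95. The cause of the changes below was not tested.

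With a −log10 q of at least 5, brain-only regions were 2338, distal-forelimb-only 820 and proximal-forelimb-only 788, and forelimb genes near the last kind 3. At equal list length, trunk-only regions were 5455, brain-only 4016 and proximal-forelimb-only 4905. Regions missing only from trunk, distal and proximal forelimb were then 2279, 1871 and 2081, and trunk regions over HoxA, HoxC and HoxD 12, 8 and 12. Telencephalon genes near brain-only regions were then 16, forelimb genes near proximal-only regions 10 and tailbud genes near trunk-only regions 11. With a common −log10 p of at least 5, brain-only regions were 4264 and distal-forelimb-only 2437. With thinning as well, trunk-only regions were 19341 and brain-only 2406, those missing only from trunk, brain and distal forelimb 682, 2956 and 1982, and HoxD regions in trunk 14. Regions missing only from trunk were 773 with summits within 100 bases and 1363 with reciprocal overlap. A 100 kb window gave 16 telencephalon genes near brain-only regions and 9 forelimb genes near proximal-only regions. Without the posterior trunk library, brain-only regions were 13863, distal-only 6182 and proximal-only 5251.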

Other observations

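The tests on the excess of trunk-only regions, the Hox test without HoxC and the draws among regions with a −log10 q of at least 5 were chosen after the result was seen. The remaining tests were chosen after the pattern but before their own result. Several 200 kb bins outside the Hox clusters held more trunk-only regions than any bin at a Hox cluster. The bins at Hoxc13 to Hoxc6 and at Hoxb9 to Hoxb1 held 14 among 20 and 13 among 27. The 200 kb bin at Sowahb, Septin11 and Ccni held 17 among 26 regions, the bin at Bcor 16 among 25, and the gene-rich bin on chromosome 17 from 25800001 15 among 30. The bins with the most brain-only regions were on chromosome Y from 6600001, with 13 of 36 regions and no listed gene, and on chromosome 6 from 130800001, with 12 of 21. Next, with 10 each, were those on chromosome 3 at Tdpoz3 and Tdpoz5, among 16, and on chromosome 4 at Zfp982 and Zfp985, among 38. As the mapping options are not given, how reads matching several places were treated is unknown. These bins were not checked for it.

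Posterior trunk had 34525 regions of its own. Depth as the whole cause would remove the excess on thinning, but 1 random thinning left 19341 against at most 3319 in another tissue. The common threshold alone left 31249. Thinning matched only the lowest backgrounds, so other differences between these single libraries were left in place and were not tested. Origin of the forelimb libraries in an earlier study as the whole cause would lengthen the brain list too. After thinning brain had 60040 peaks against 62005 in the longer forelimb list, but as deposited it had 74127 against 64793. Study and depth run together here, so thinning removes part of what was to be tested. Brain is also 1 library of another tissue, so its list length cannot decide the question. The 2406 brain-only regions left after thinning do not count the 2948 called in trunk and brain alone. Origin in an earlier study thus stays open. A longer tail of weak calls stays open too, since the 86.1% of trunk-only regions that ranked below the length of the shortest list, and the equal-length count of 5455, are largely fixed by how such regions and lists are chosen, and tissue and stage are untested.

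The Hox clusters had 41 trunk-only regions. Random windows matched on shared regions reached 20 at the upper end of their central 95%, and those matched on gene ends 22, which argues against chance placement and gene density. Depth does not account for the sum either, which was 20 after thinning against 13 at the same bound. Without HoxC the thinned count was 11, at percentile 97.1, which leaves depth open for HoxA, HoxB and HoxD. Their counts of 7 at equal length and 20 at the stricter q stood at 99.86 and 99.94. Neither of these settings matches depth, so they do not decide the question. HoxC alone stood at 99.98 after thinning, and whether tissue underlies this was not tested.

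Among the 10 strongest distal-forelimb-only regions, those at Cdx4, Meis1 and Hoxa13 lie near listed developmental genes. Shallow coverage elsewhere would not explain them, as distal forelimb was the shallowest library and the others had 1.08 to 2.21 times its relative depth. The lowest chance of a call in another library at equal occupancy was 1 to the precision computed. That outcome was largely fixed in advance by the order of depths, so it adds no support. In 10000 draws of 10 such regions, 0.02% had 3 or more near a listed gene, and 0.03% among the 545 with a −log10 q of at least 5. That floor lies below the regions at Cdx4, Hoxa13 and Meis1, whose −log10 q were 24.0, 20.3 and 21.6. Strength was thus matched only in part. The draws were made because these regions had been noticed in 1 of the 4 tissues, the others having 0 such regions among their leading 10, so the shares overstate how rare the pattern is. Whether CTCF binding there differs by tissue was not tested, with 1 library each.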
